A study of Caenorhabditis elegans with 40 samples.

How the data were processed

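The series holds 40 RNA sequencing libraries of whole C. elegans in 8 groups of 5, made from poly(A) RNA with a stranded kit, with animals kept on E. coli OP50. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned with HISAT2 2.2.1, counted per gene with featureCounts and compared with DESeq2 1.31.16. The deposited files are 9 tables, 1 per comparison, each with 42048 features and 10 sample columns. Their sample columns hold signal per gene that the authors had divided by DESeq2 size factors within each table, so the values are normalized counts, not raw reads. The tables also hold log2 fold changes that the authors computed with DESeq2 and p-values that the authors computed and adjusted with the same tool. These p-values were used here only to compare the called genes. The authors' fold changes were used only to compare the signs of called genes and to check the column names. The submitters' notes do not say how multi-mapped reads were counted, so genes with near-identical copies, such as msp genes, vit-3, vit-4 and vit-5, have uncertain single values. Genes are given by the symbols of the files, 38832 of which match the reference annotation, and no coordinates are given because the submitters' notes name another genome build than the annotation used here.

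Whole reads were recovered from the normalized values by finding the factor of each column that makes its values whole numbers. All values were whole within 0.001 reads, with size factors from 0.798 to 1.259. The 90 sample columns were matched across tables by their recovered reads, and 70 pairs of columns were identical. In the table of octr-1 mutants at 25 and 20 °C, 10 columns were identical to libraries of the other group in 2 other tables each. Their group names were therefore exchanged before testing, and the values with the names as given are in the closing section. Depth was 27.9 to 41.0 M reads assigned to genes per library. Beyond counting error, the median coefficient of variation between replicates was 2.06% to 4.82% in genes with over 1000 reads.

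Because the values are normalized, each of the 9 comparisons was tested within its own table with limma-trend (limma 3.58.1, robust, R 4.3.3) on log2(value + 1). Before the data were examined, the plan was edgeR on raw counts, with limma foreseen for normalized values. Genes with a value of at least 10 in at least 5 libraries were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Folds are 2 to the power of the log2 fold change on this scale, which understates changes of low genes. A genotype effect was compared between 2 conditions as the difference of the 2 log2 fold changes over the root of their summed squared standard errors. The age comparisons within a genotype and the comparison of the wild type at 25 and 20 °C have no table of their own and were tested with edgeR 4.0.16 (quasi-likelihood, TMM) on the recovered reads. The gene lists, the alternatives of the closing section and the rule for named genes were fixed before the data were examined, except where the text says otherwise.

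Of 43 gene lists, 42 were tested with camera at a preset correlation of 0.01 and with an estimated one. The list of intracellular pathogen response genes was not tested because no member matched by name. Each list is given with its members called higher and lower over all genes and adjusted over the list alone. The rule for named genes was octr-1 in every comparison, then the 6 largest rises and 6 deepest falls among called genes with a mean of at least 2 log2 CPM and no overlap between groups. It further named the 3 members of smallest p in up to 8 lists per comparison past camera at the preset correlation, and the 6 genes of smallest p in each test of a difference between genotype effects. Other lists are given only where they passed with the estimated correlation. In the 3 comparisons on recovered reads, these lists are given without their members and only some of the single genes are named. Alternatives were edgeR with TMM or RLE, DESeq2 1.42.0, no filter on low values, a pseudocount of 0.1, a replicate block, all groups in 1 fit, library size as the only scaling, and leaving out each library. Tables and figures used numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

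The tests were also tried on simulated data with 200 changed genes. At changes of 1.25, 1.5 and 2-fold, limma found 62.7%, 88.1% and 97.0% in the young comparison and 74.6%, 85.1% and 100.0% in the genotype comparison at 25 °C. It found 58.2%, 89.6% and 97.0% in the wild type at 15 and 20 °C, and 74.6%, 91.0% and 100.0% in mutants at 25 and 20 °C. Tests of a difference between genotype effects found 46.3%, 85.1% and 92.4% for 25 against 20 °C. For age they found 44.8%, 73.1% and 75.8%, the lowest shares of the 6 simulations, so the count for age misses part of the 2-fold differences. Changed genes that failed the filter on low values counted as not found, and 12958 simulated genes were tested for age against 15376 for 25 against 20 °C. Misses by the filter and by the test were not separated. Before the result for age was seen, the simulation was to stop below 80% of the 2-fold changes. After it was seen, this limit was dropped and a limit on bias and false calls used instead. Between 3.2% and 5.9% of the limma calls were false, with up to 5.8% for edgeR and 7.9% for DESeq2. Only 200 genes changed, in random directions, so false calls from a shift of many genes together were not measured. With 1 gene list raised, camera found it and called 0 of the other lists at the preset correlation, in each of 2 comparisons. The simulated genes varied independently, so this does not show how many lists are called by chance where genes correlate. Random regroupings of the real libraries called a median of 13 lists in the young comparison and 16 in the genotype comparison at 25 °C. The labels give no batch and no other study data were used here.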

Results

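Polyadenylated RNA of whole Caenorhabditis elegans was sequenced in 40 libraries, in 8 groups of 5 replicates. Wild-type N2 animals and octr-1 mutants carrying the ok371 allele were each collected as young adults at 20 °C and as old adults at 15, 20 and 25 °C. The old animals were collected on day 24 of adulthood at 15 °C, day 14 at 20 °C and day 9 at 25 °C, so every comparison of temperatures among old animals also compares different days. By its title, the series addresses how temperature, aging and OCTR-1, a neuronal G protein-coupled receptor for octopamine, relate to each other at the level of RNA. The libraries held between 27.9 and 41.0 M reads assigned to genes. Young libraries had reads in 17136 to 18406 features and old libraries in 21265 to 23755. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

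octr-1 itself was low in every library and lower in each mutant group than in its wild-type partner. In young adults it had 1.251 ± 0.168 CPM in the wild type and 0.377 ± 0.11 in the mutant (mean ± SD, n = 5 each, scaled by library size alone), from 27 to 51 reads and 10 to 19 reads per library. In old wild-type animals octr-1 stood at 6.12 ± 0.34 CPM at 15 °C, 6.56 ± 0.428 at 20 °C and 6.90 ± 0.195 at 25 °C. The old mutants had 1.42 ± 0.19, 0.981 ± 0.144 and 1.18 ± 0.149 at the same temperatures. octr-1 was thus 3.42-fold lower in young mutants and 6.65-fold, 4.26-fold and 6.63-fold lower in old ones at 20, 15 and 25 °C (limma adjusted p = 4.5e-06, 4.04e-13, 4.86e-11 and 1.2e-17). All 5 mutant libraries lay below all 5 wild-type libraries in each of the 4 genotype comparisons. Reads remained in the mutants, and the counts per gene do not show whether these fell inside or outside the deleted part of the gene.

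**Figure D1:**
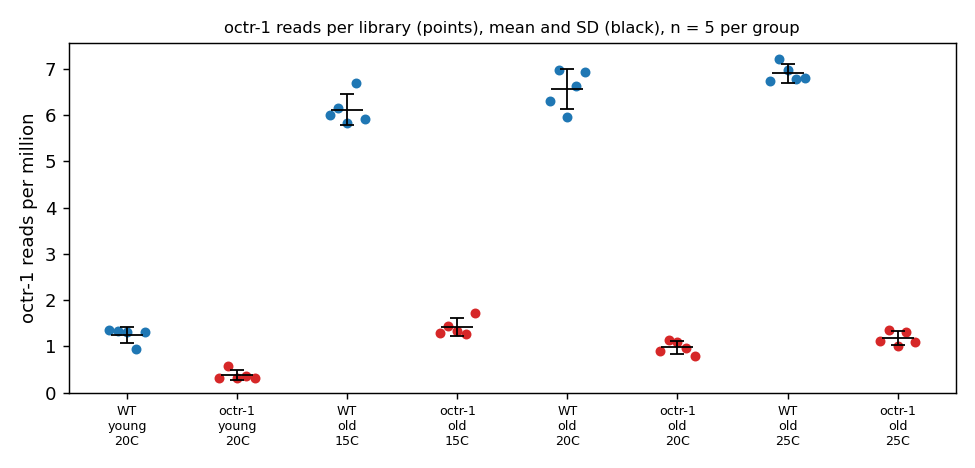
octr-1 CPM in each library (points, 5 per group, wild type in blue and octr-1 mutant in red), with the group mean and SD in black. The mutant means lie between 0.377 and 1.42, and the means of the old wild-type groups between 6.12 and 6.90.

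The first comparison set octr-1 mutants against the wild type in young adults at 20 °C, and genes of sperm were the list with the smallest p at camera's preset correlation, though not with an estimated one. Of 60 measured major sperm proteins, which form the sperm cytoskeleton, and other sperm genes, 50 were higher and 4 lower in the mutant (51 and 5 adjusted over the list alone), with a median log2 fold change of 1.48 (camera adjusted p = 6.76e-15, and adjusted p = 0.441 with an estimated correlation). gsp-3, a sperm-specific protein phosphatase, rose 3.05-fold, from 28.9 ± 11 to 89.4 ± 26.6 normalized reads (SD, n = 5), msp-64 2.72-fold and msp-38 2.81-fold. Replicate 1 of the young wild type stood above the other 4 in TMM-scaled CPM, for gsp-3 at 1.99 against 0.893 to 1.06, msp-38 at 2.75 against 1.12 to 1.56, msp-55 at 5.21 against 2.19 to 3.02 and gipc-2 at 8.47 against 3.35 to 4.42. The msp genes are nearly identical to each other, which leaves the values of single members uncertain. Among genes with a mean of at least 2 log2 CPM and no overlap between the groups, the largest rises, as log2 fold change ± SE, were in col-147 (1.93 ± 0.31), asp-12 (1.93 ± 0.12), F53A9.8 (1.88 ± 0.15), msp-55 (1.83 ± 0.26), R09E10.6 (1.82 ± 0.32) and gipc-2 (1.76 ± 0.31). Of these, col-147 is a cuticle collagen and asp-12 an aspartyl protease. The deepest falls within the same limits were in haf-6, an ABC transporter, at 3.96-fold (401 ± 9.26 against 1591 ± 89.8 normalized reads), and in scl-2 (-1.30 ± 0.09), lys-7 (-1.28 ± 0.32), Y69A2AR.12 (-1.02 ± 0.10), T03D3.5 (-0.95 ± 0.05) and col-95 (-0.88 ± 0.07), where lys-7 is an antimicrobial lysozyme. The limma adjusted p of these 12 genes was at most 0.0125.

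Cuticle collagens, the structural proteins of the worm's outer layer, had more members higher than lower in young mutants (50 higher and 6 lower of 112 measured, 53 and 6 adjusted over the list alone, median 0.58, camera adjusted p = 4.59e-09, and adjusted p = 0.441 with an estimated correlation). col-133 rose 4.72-fold and col-118 1.64-fold, while col-95 fell 1.84-fold. Nuclear hormone receptors, a large family of transcription factors, counted 64 higher and 3 lower of 177 measured, 61 and 3 adjusted over the list alone, with adjusted p = 0.0428 also with an estimated correlation. Here nhr-31, nhr-181 and nhr-101 rose 1.32-fold, 1.48-fold and 1.4-fold. UDP-glucuronosyltransferases, which conjugate xenobiotics, counted 26 higher and 4 lower of 54 measured, 28 and 7 adjusted over the list alone (camera adjusted p = 1.47e-05, and adjusted p = 0.373 with an estimated correlation). Among them ugt-6 rose 2.51-fold and ugt-41 1.79-fold, and ugt-63 fell 1.44-fold. Glutathione S-transferases, another detoxification family, had 15 of 32 members higher and 0 lower (16 higher adjusted over the list alone), with adjusted p = 0.0428 with an estimated correlation.

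Proteasome subunits had 27 of 32 members lower and 0 higher in young mutants (29 lower adjusted over the list alone), with a median log2 fold change of -0.17 (camera adjusted p = 2.53e-08, and adjusted p = 0.446 with an estimated correlation). Here rpn-9, rpn-5 and rpn-10 of the regulatory particle were 1.17-fold, 1.16-fold and 1.17-fold lower. Cytosolic ribosomal proteins counted 1 higher and 50 lower of 78 measured, 1 and 53 adjusted over the list alone, around a median of -0.15 (camera adjusted p = 6e-08, and adjusted p = 0.52 with an estimated correlation). Of these, rps-10 (1.21-fold), rps-0 (1.15-fold) and rpl-20 (1.17-fold) were lower. Germline stem cell and meiosis genes counted 1 higher and 23 lower of 35 measured, 1 and 25 adjusted over the list alone (camera adjusted p = 7.39e-07, and adjusted p = 0.373 with an estimated correlation), among them the germline helicase glh-4 (1.2-fold lower) and the Argonautes wago-1 (1.19-fold) and csr-1 (1.16-fold). Oocyte and eggshell genes counted 1 higher and 21 lower of 27 measured, 1 and 22 adjusted over the list alone (camera adjusted p = 2.68e-06, and adjusted p = 0.446 with an estimated correlation). Here the RNA-binding proteins mex-1, mex-3 and puf-3 were 1.26-fold, 1.23-fold and 1.23-fold lower. The medians of these 4 lists depended on scaling, and with library size as the only scaling they were -0.071 for proteasome, -0.048 for ribosomal, -0.046 for germline and -0.068 for oocyte genes. In all, 5722 of 13122 tested genes passed limma's test at an adjusted p under 0.05, 2572 higher and 3150 lower, and 499 of the higher and 38 of the lower ones changed at least 2-fold. Of the called genes 44.9% were higher with limma, 44.8% with DESeq2, 48.9% with edgeR and RLE and 52.7% with edgeR and TMM, so the more frequent direction depended on the scaling. In 5 of the 9 comparisons, this one included, at least 5% of random regroupings of the 10 libraries gave as many gene lists at camera's preset correlation as the real groups, so in these 5 the number of list calls alone does not separate the groups from chance.

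**Figure D2:**
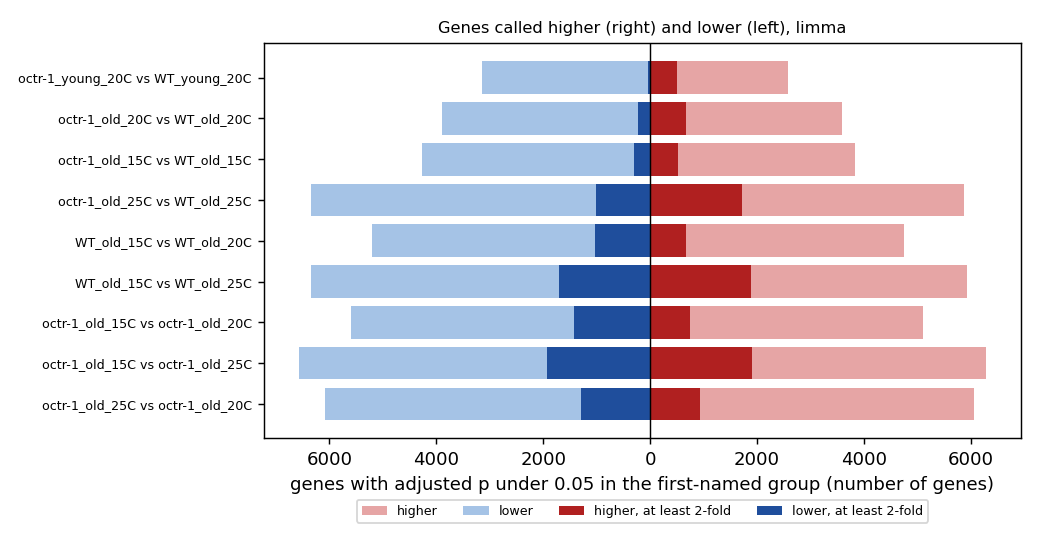
Number of genes with a limma adjusted p under 0.05 in each of the 9 comparisons (x axis, number of genes, higher in the first-named group to the right and lower to the left), with the share changed at least 2-fold in dark colours. The genotype comparison at 25 °C has 12212 called genes, against 5722 in young animals.

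In old animals at 20 °C the sperm genes were again higher in octr-1 mutants (55 higher and 0 lower of 61 measured, 56 and 0 adjusted over the list alone, median 1.94, camera adjusted p = 4.79e-25, and adjusted p = 0.172 with an estimated correlation). msp-55 rose 6.28-fold, from 12 ± 2.51 to 80.7 ± 17 normalized reads (SD, n = 5), msp-57 5.73-fold and msp-40 4.75-fold. PMK-1 immune effectors, outputs of the p38 MAP kinase pathway, had 14 of 19 members lower and 0 higher (14 lower adjusted over the list alone, camera adjusted p = 5.11e-07, and adjusted p = 0.172 with an estimated correlation). Here F08G5.6 (2.41-fold), lys-2 (1.84-fold) and thn-2 (1.84-fold) were lower. The lysozyme and saposin-like list also holds lys-2, so it is not independent of the PMK-1 list in this or the later comparisons. The lysozyme and saposin-like list counted 7 higher and 20 lower of 32 measured, 7 and 20 adjusted over the list alone (camera adjusted p = 7.4e-06, and adjusted p = 0.388 with an estimated correlation), led by the lysozyme lys-7, which fell 3.49-fold from 13310 ± 655 to 3816 ± 278 normalized reads, and by lys-10 (9.29-fold) and spp-14 (1.87-fold). C-type lectins, secreted sugar-binding proteins, counted 19 higher, 53 lower and 47 not called, with 19 and 53 adjusted over the list alone (camera adjusted p = 0.00105, and adjusted p = 0.172 with an estimated correlation). Of these, clec-41 (2.28-fold), clec-47 (2.07-fold) and clec-65 (1.65-fold) were lower.

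All 6 vitellogenins, the yolk proteins made in the intestine, were lower in the old mutants at 20 °C (6 adjusted over the list alone), with a median log2 fold change of -0.78 (camera adjusted p = 7.4e-06, and adjusted p = 0.513 with an estimated correlation). Here vit-3 (2.77-fold), vit-4 (2.23-fold) and vit-1 (1.96-fold) were lower. Collagens counted 15 higher and 55 lower of 120 measured, 15 and 55 adjusted over the list alone (camera adjusted p = 9.87e-06, and adjusted p = 0.543 with an estimated correlation). Here col-80 (3.59-fold), col-101 (3.37-fold) and col-106 (2.31-fold) fell. Ribosomal proteins counted 28 higher and 0 lower of 78 measured, 22 and 0 adjusted over the list alone, around a median of 0.11 (camera adjusted p = 9.08e-05, and adjusted p = 0.666 with an estimated correlation). Of these, rpl-31 (1.23-fold), rpl-5 (1.16-fold) and rpl-1 (1.30-fold) were higher. Subunits of the electron transport chain and ATP synthase counted 0 higher and 16 lower of 32 measured, 0 and 17 adjusted over the list alone (camera adjusted p = 0.00159, and adjusted p = 0.566 with an estimated correlation). Here cco-1 of complex IV, mev-1 of complex II and nuo-3 of complex I were 1.23-fold, 1.21-fold and 1.17-fold lower.

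Among single genes with a mean of at least 2 log2 CPM and no overlap, the largest rises in old mutants at 20 °C, as log2 fold change ± SE, were in ZK355.3 (3.28 ± 0.12), Y54G2A.57 (2.35 ± 0.09), R09E10.6 (2.33 ± 0.12), ZK355.8 (2.3 ± 0.11), gipc-1 (2.22 ± 0.12) and Y41C4A.11 (2.12 ± 0.05). ZK355.3 went from 62.0 ± 13.2 to 603 ± 73 normalized reads. The deepest falls within these limits were in srw-85, a predicted chemoreceptor, the insulin-like peptide ins-19 and the saposin-like spp-17, with the full set being srw-85 (-2.62 ± 0.08), fip-2 (-2.25 ± 0.08), C45B2.1 (-2.14 ± 0.11), ins-19 (-2.09 ± 0.11), spp-17 (-2.06 ± 0.09) and T28A11.19 (-2.05 ± 0.08). Each had a limma adjusted p of at most 2.11e-11. The genotypes differed in 7492 of 15762 tested genes (3596 higher and 3896 lower), of which 667 were at least 2-fold higher and 219 at least 2-fold lower.

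At 15 °C, where animals were collected on day 24, the sperm list of old octr-1 mutants against the wild type counted 51 higher and 1 lower of 59 measured, 52 and 1 adjusted over the list alone, with a median of 1.38 (camera adjusted p = 8.25e-16, and adjusted p = 0.388 with an estimated correlation). Here the phosphatase gsp-4 rose 3.19-fold, from 35.4 ± 9.51 to 112 ± 10.2 normalized reads (SD, n = 5), msp-57 3.24-fold and ssp-35 1.75-fold. Antimicrobial peptides of the caenacin, neuropeptide-like and abf families had 20 of 23 members lower and 0 higher (20 lower adjusted over the list alone, camera adjusted p = 6.21e-08, and adjusted p = 0.388 with an estimated correlation). abf-2 fell 3.63-fold, from 923 ± 54.7 to 254 ± 15.4 normalized reads, cnc-2 2.57-fold and nlp-28 2.06-fold. Lysozymes and saposin-like proteins counted 1 higher and 25 lower of 32 measured, 1 and 26 adjusted over the list alone (camera adjusted p = 3.31e-08, and adjusted p = 0.388 with an estimated correlation). Of these, spp-9 (6.59-fold), lys-7 (2.04-fold) and lys-3 (2.0-fold) were lower.

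Intestine genes had 15 of 21 members lower and 0 higher in the old mutants at 15 °C (15 lower adjusted over the list alone, camera adjusted p = 1.98e-05, and adjusted p = 0.684 with an estimated correlation). This includes the intestinal GATA factor elt-2 at 2.27-fold lower, the lipid-binding lbp-6 at 2.0-fold lower and the ferritin ftn-1 at 1.78-fold lower. UDP-glucuronosyltransferases counted 5 higher and 32 lower of 59 measured, 5 and 32 adjusted over the list alone (camera adjusted p = 0.00043, and adjusted p = 0.684 with an estimated correlation). Here ugt-63 (3.38-fold), ugt-62 (1.68-fold) and ugt-48 (1.56-fold) fell. Collagens counted 7 higher and 57 lower of 120 measured, 8 and 57 adjusted over the list alone (camera adjusted p = 1.96e-05, and adjusted p = 0.684 with an estimated correlation). Of these, the adult collagen col-19 (3.11-fold), col-106 (2.39-fold) and col-8 (2.16-fold) were lower. Ribosomal proteins counted 1 higher and 47 lower of 78 measured, 1 and 48 adjusted over the list alone, around a median of -0.18 (camera adjusted p = 1.46e-06, and adjusted p = 0.684 with an estimated correlation). Here rpl-29 (1.30-fold), rps-19 (1.29-fold) and rpl-34 (1.24-fold) were lower. Synaptic machinery had more members higher than lower (18 higher and 3 lower of 30 measured, 19 and 3 adjusted over the list alone, camera adjusted p = 0.000356, and adjusted p = 0.388 with an estimated correlation). Of these, the vesicle priming factor unc-13 (1.68-fold), the active-zone protein unc-10 (1.72-fold) and the calcium channel unc-2 (1.48-fold) were higher.

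With a mean of at least 2 log2 CPM and no overlap, the largest single rises at 15 °C were in R09E10.6 (2.07 ± 0.20), gipc-2 (2.05 ± 0.21), T10E9.4 (1.98 ± 0.15), gipc-1 (1.67 ± 0.14), Y57G11A.2 (1.5 ± 0.11) and F49C12.15 (1.44 ± 0.11), and the deepest falls in srw-85 (-2.14 ± 0.08), C17F4.7 (-1.96 ± 0.17), F23D12.11 (-1.96 ± 0.12), T28A11.19 (-1.94 ± 0.10), abf-2 (-1.86 ± 0.06) and C54D10.3 (-1.83 ± 0.11), as log2 fold change ± SE. R09E10.6, gipc-1 or gipc-2 thus stood among the 6 largest rises within these limits in young animals and in old animals at 15 and 20 °C. With limma, 8102 of 15856 tested genes passed, 3827 higher and 4275 lower, 521 and 304 of them by at least 2-fold.

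The genotype effect in old animals at 25 °C included falls of collagens, vitellogenins, aspartyl and cysteine proteases and PMK-1 immune effectors. Of 130 collagens 110 were lower and 8 higher (110 and 8 adjusted over the list alone), with a median log2 fold change of -2.01 (camera adjusted p = 7.44e-16, and adjusted p = 0.0778 with an estimated correlation). col-20 fell from 1516 ± 67 to 16 ± 4.93 normalized reads (SD, n = 5), a 90.1-fold difference, and col-140 (41.6-fold), col-124 (31.9-fold) and col-95 (5.2-fold) were lower. acdh-1, an acyl-CoA dehydrogenase of the propionate shunt, fell 61.3-fold, from 4318 ± 278 to 70 ± 10.5 normalized reads. Among genes with a mean of at least 2 log2 CPM and no overlap, the 6 deepest falls, as log2 fold change ± SE, were in col-20 (-6.49 ± 0.14), acdh-1 (-5.94 ± 0.08), col-19 (-5.87 ± 0.20), col-80 (-5.75 ± 0.18), vit-3 (-5.65 ± 0.12) and col-140 (-5.38 ± 0.08). All 6 vitellogenins were lower (6 adjusted over the list alone, camera adjusted p = 8.64e-07, and adjusted p = 0.0794 with an estimated correlation). Here the abundant vit-6, vit-2 and vit-5 were 5.74-fold, 5.26-fold and 4.37-fold lower.

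The lysozyme and saposin-like list counted 3 higher and 28 lower of 33 measured, 3 and 28 adjusted over the list alone at 25 °C, with a median of -2.06 and adjusted p = 0.00785 with an estimated correlation. lys-7 fell 11.9-fold, from 30930 ± 1069 to 2598 ± 158 normalized reads, lys-4 25.6-fold and spp-5 6.60-fold. PMK-1 immune effectors counted 2 higher and 16 lower of 19 measured, 2 and 16 adjusted over the list alone (adjusted p = 0.00679 with an estimated correlation). Of these, lys-2 (13.9-fold), thn-2 (10.6-fold) and T24B8.5 (7.23-fold) were lower. Aspartyl and cysteine proteases, the digestive and lysosomal cathepsins, counted 1 higher and 21 lower of 23 measured, 1 and 21 adjusted over the list alone (adjusted p = 0.00507 with an estimated correlation). Here asp-2, cpr-6 and asp-4 fell 13.5-fold, 4.72-fold and 3.83-fold. Intestine genes, a list that shares asp-1, asp-5, cpr-1 and cpr-6 with the proteases, counted 1 higher and 20 lower of 21 measured, 1 and 20 adjusted over the list alone (adjusted p = 0.014 with an estimated correlation). Here cpr-1 and asp-5 fell 7.68-fold and 5.16-fold.

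Sperm genes were higher at 25 °C too (59 higher and 2 lower of 64 measured, 59 and 2 adjusted over the list alone, median 1.4, adjusted p = 0.00679 with an estimated correlation). Of these, msp-57 (3.90-fold), msd-4 (2.98-fold) and ssp-35 (2.50-fold) were higher. Male neuron genes, tested only after the result was seen, had a median log2 fold change of 1.32 over 9 measured genes in the same comparison, 7 of them called higher and 0 lower. They ran from lov-1 at 1.70 ± 0.14 (SE) to cwp-4 at 0.07 ± 0.18 and pkd-2 at 0.48 ± 0.26, which were not called (limma adjusted p = 0.721 and 0.0934). Their medians were 0.51 over 8 at 20 °C (3 higher and 0 lower) and 0.54 over 9 at 15 °C (5 higher and 0 lower). Oocyte and eggshell genes were lower (0 higher and 26 lower of 27 measured, 0 and 26 adjusted over the list alone, camera adjusted p = 1.19e-08, and adjusted p = 0.0808 with an estimated correlation), among them the yolk receptor rme-2 at 2.11-fold, the eggshell protein cbd-1 at 2.07-fold and the caveolin cav-1 at 1.98-fold. Nuclear hormone receptors counted 128 higher and 33 lower of 211 measured, 128 and 33 adjusted over the list alone, with adjusted p = 0.00507 with an estimated correlation. The largest single rises within the limits above were in C01G10.5 (4.48 ± 0.11), C15H9.11 (3.57 ± 0.05), Y37H2C.1 (3.48 ± 0.07), T28B4.4 (3.30 ± 0.05), cnc-1 (2.87 ± 0.07) and Y46H3A.5 (2.79 ± 0.06), as log2 fold change ± SE, where cnc-1 encodes a caenacin antimicrobial peptide. In all 12212 of 15964 tested genes passed limma's test, 5877 higher and 6335 lower, and 1714 rose and 1012 fell at least 2-fold. Dividing by library size alone, without composition factors, moved the median log2 fold change of all genes from -0.0127 to 0.1958, and each list tested with camera and named for this comparison kept the sign of its median under that scaling. The median of the oocyte list went from -0.469 to -0.259 and that of the intestine list from -0.591 to -0.382.

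**Figure D3:**
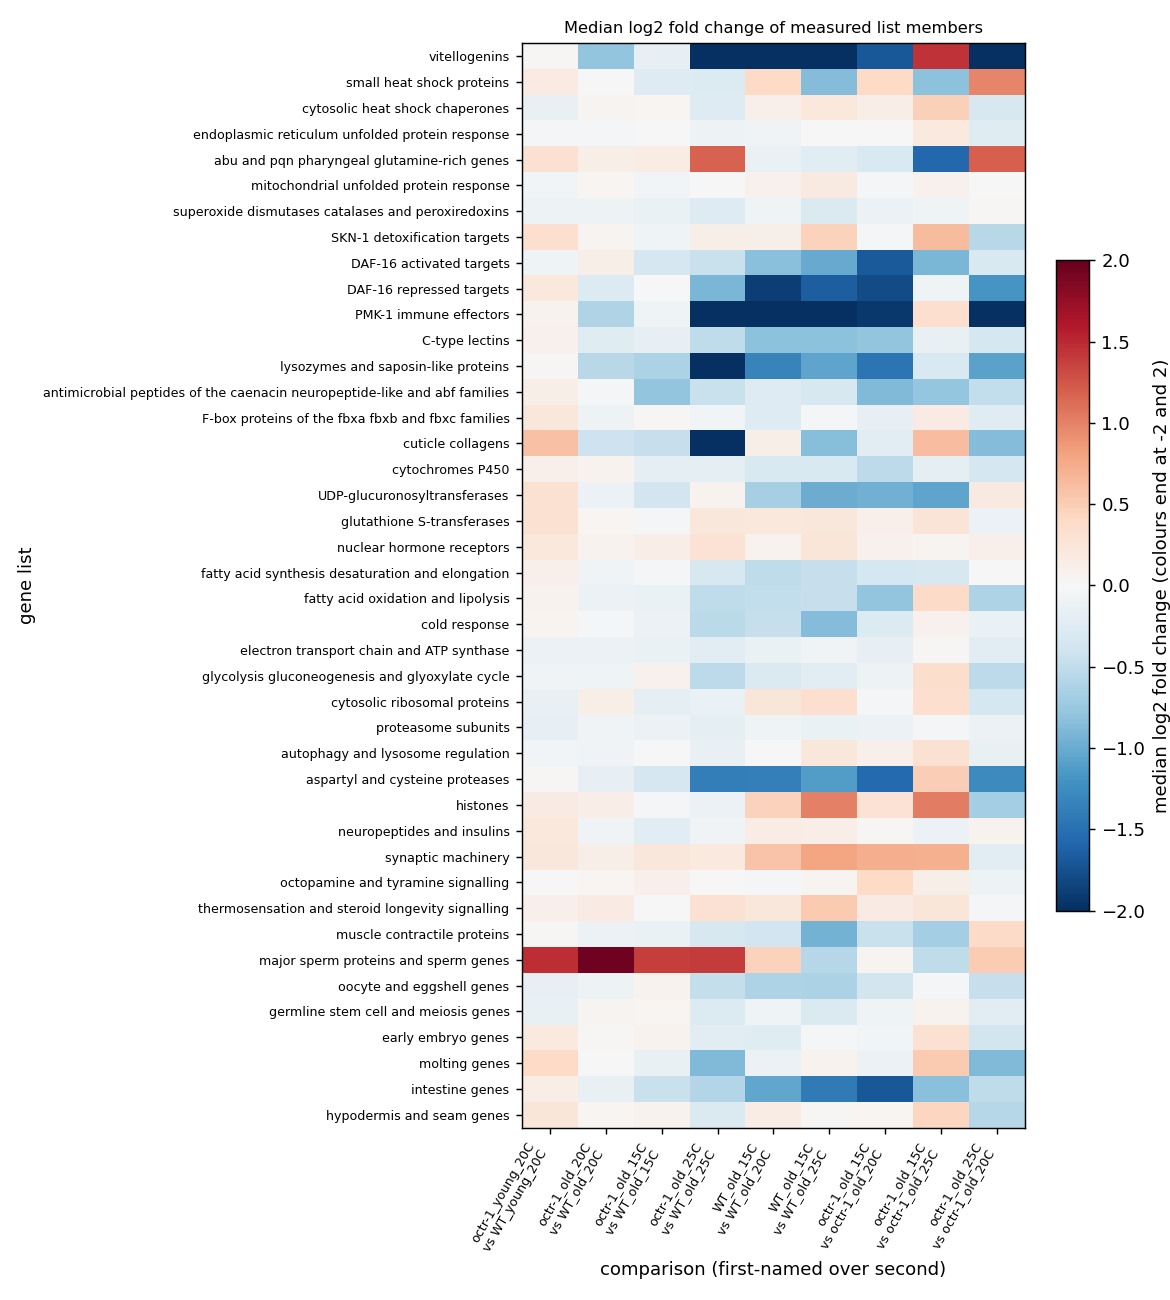
Median log2 fold change of the measured members of each of the 42 tested gene lists (rows) in each of the 9 comparisons (columns, first-named group over second), with colours ending at -2 and 2. The sperm list has medians of 1.48, 1.94, 1.38 and 1.4 in the 4 genotype comparisons, in the order of the columns.

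Old wild-type animals at 15 °C were compared with old wild-type animals at 20 °C. Every one of the 19 measured PMK-1 immune effectors was lower (19 adjusted over the list alone), with a median log2 fold change of -2.05 and adjusted p = 0.0111 with an estimated correlation. T24B8.5, a reporter gene of this pathway, was 13.3-fold lower (67.4 ± 13 against 902 ± 113 normalized reads, SD, n = 5), lys-2 6.95-fold and thn-2 3.10-fold. C-type lectins counted 15 higher and 74 lower of 117 measured, 15 and 74 adjusted over the list alone (adjusted p = 0.0211 with an estimated correlation). Of these, clec-47 (22.7-fold), clec-41 (7.30-fold) and clec-65 (5.80-fold) were lower. Lysozymes and saposin-like proteins counted 2 higher and 25 lower of 32 measured, 2 and 25 adjusted over the list alone (camera adjusted p = 8.69e-10, and adjusted p = 0.0594 with an estimated correlation). Here lys-7, lys-1 and ilys-5 were 6.65-fold, 4.86-fold and 4.66-fold lower. Targets that the FOXO factor DAF-16 represses counted 0 higher and 10 lower of 13 measured, 0 and 10 adjusted over the list alone, with adjusted p = 0.0199 with an estimated correlation.

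Aspartyl and cysteine proteases had 21 of 22 members lower and 0 higher in the wild type at 15 °C than at 20 °C (21 lower adjusted over the list alone, camera adjusted p = 2.4e-12, and adjusted p = 0.0594 with an estimated correlation). Of these, asp-13 (6.89-fold), asp-2 (4.40-fold) and cpr-6 (3.34-fold) were lower. Intestine genes counted 2 higher and 18 lower of 21 measured, 2 and 18 adjusted over the list alone (camera adjusted p = 5.87e-09, and adjusted p = 0.0594 with an estimated correlation). This includes the proton pump subunit vha-6 at 3.33-fold lower and the desaturase fat-2 at 2.38-fold lower. Oocyte and eggshell genes counted 1 higher and 25 lower of 27 measured, 1 and 25 adjusted over the list alone (camera adjusted p = 3.44e-10, and adjusted p = 0.109 with an estimated correlation). Of these, the eggshell proteoglycan cpg-3, the chitin synthase chs-1 and the maternal RNA-binding protein spn-4 were 1.98-fold, 1.80-fold and 1.82-fold lower. Synaptic machinery had 27 of 31 members higher and 0 lower (27 higher adjusted over the list alone, camera adjusted p = 6.56e-08, and adjusted p = 0.0594 with an estimated correlation). Of these, ric-19 (2.25-fold), unc-31 (1.90-fold) and unc-2 (1.81-fold) were higher. Ribosomal proteins counted 63 higher and 0 lower of 78 measured, 64 and 0 adjusted over the list alone, with a median of 0.24 (camera adjusted p = 3.22e-09, and adjusted p = 0.507 with an estimated correlation). Here rpl-24.2, rpl-12 and rpl-41 were 1.61-fold, 1.41-fold and 1.30-fold higher.

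Among genes with a mean of at least 2 log2 CPM and no overlap, those that rose the most in the wild type at 15 °C over 20 °C were F40H7.12 (3.56 ± 0.10), Y71H2AR.2 (3.37 ± 0.12), Y71H2AM.25 (2.72 ± 0.07), fbxa-43 (2.55 ± 0.09), trpl-5 (2.42 ± 0.07) and F56A6.5 (2.41 ± 0.08), as log2 fold change ± SE, where fbxa-43 encodes an F-box protein and trpl-5 a TRP channel. Those that fell the most within these limits were clec-47 (-4.51 ± 0.12), dod-24 (-4.09 ± 0.16), F55G11.4 (-4.04 ± 0.11), T24B8.5 (-3.73 ± 0.11), C14C6.5 (-3.64 ± 0.15) and ilys-3 (-3.49 ± 0.09). octr-1 stood at 185 ± 9.0 against 206 ± 13 normalized reads, which limma did not separate (adjusted p = 0.093). A total of 9949 of 15563 tested genes differed, 4750 higher and 5199 lower at 15 °C, 678 and 1036 of them by at least 2-fold.

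Between 15 °C and 25 °C, old wild-type animals were compared with the same 5 libraries at 15 °C as before. Synaptic machinery had 27 of 30 members higher and 0 lower at 15 °C (27 higher adjusted over the list alone, adjusted p = 0.0134 with an estimated correlation). Of these, ric-19 and ida-1 of dense-core vesicles and unc-2 were 3.56-fold, 2.53-fold and 3.07-fold higher. Histones counted 33 higher and 2 lower of 38 measured, 33 and 2 adjusted over the list alone (camera adjusted p = 4.96e-07, and adjusted p = 0.204 with an estimated correlation). Here the linker histones hil-3, hil-2 and hil-7 rose 5.53-fold, 4.41-fold and 4.03-fold, hil-3 from 1178 ± 24.4 to 6523 ± 386 normalized reads (SD, n = 5). Ribosomal proteins counted 71 higher and 1 lower of 78 measured, 71 and 1 adjusted over the list alone, with a median of 0.34 (camera adjusted p = 4e-10, and adjusted p = 0.41 with an estimated correlation). Here rpl-24.2 (2.05-fold), rpl-12 (1.87-fold) and rpl-22 (1.56-fold) were higher. Oocyte and eggshell genes counted 2 higher and 24 lower of 27 measured, 2 and 24 adjusted over the list alone (camera adjusted p = 1.31e-06, and adjusted p = 0.204 with an estimated correlation), yet cav-1 was 4.21-fold higher at 15 °C, while chs-1 and spn-4 were 2.13-fold and 1.84-fold lower.

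PMK-1 immune effectors counted 1 higher and 16 lower of 18 measured, 1 and 16 adjusted over the list alone at 15 °C against 25 °C (adjusted p = 0.0238 with an estimated correlation). Of these, T24B8.5 (15.6-fold), lys-2 (4.88-fold) and C17H12.8 (3.73-fold) were lower. The lysozyme and saposin-like list counted 2 higher and 26 lower of 32 measured, 2 and 26 adjusted over the list alone (camera adjusted p = 1.73e-06, and adjusted p = 0.118 with an estimated correlation). lys-7 was 15.2-fold lower (1901 ± 55.7 against 28860 ± 1119 normalized reads), lys-1 5.09-fold and spp-15 2.66-fold. Proteases counted 2 higher and 20 lower of 22 measured, 2 and 20 adjusted over the list alone (camera adjusted p = 1.73e-06, and adjusted p = 0.0994 with an estimated correlation). Of these, asp-2 (5.52-fold), cpr-6 (3.27-fold) and asp-6 (2.71-fold) were lower. Intestine genes counted 2 higher and 18 lower of 21 measured, 2 and 18 adjusted over the list alone (camera adjusted p = 3.08e-06, and adjusted p = 0.0879 with an estimated correlation). Here vha-6 and fat-2 were 4.09-fold and 3.71-fold lower. Within the limits on mean and overlap, the largest rises were in F40H7.12 (5.10 ± 0.12), F56A6.5 (4.91 ± 0.19), fbxa-43 (4.26 ± 0.11), Y71H2AM.25 (3.87 ± 0.07), fmo-2 (3.46 ± 0.09) and gst-30 (3.45 ± 0.10), as log2 fold change ± SE, where fmo-2 is a flavin monooxygenase and gst-30 a glutathione S-transferase. The deepest falls within them were in ilys-2 (-4.89 ± 0.10), C50F7.5 (-4.85 ± 0.14), F55G11.4 (-4.52 ± 0.09), ilys-3 (-4.33 ± 0.10), col-20 (-4.0 ± 0.18) and T24B8.5 (-3.97 ± 0.10), where ilys-2 and ilys-3 are invertebrate lysozymes. octr-1 was slightly lower at 15 °C (1.15-fold, limma adjusted p = 0.00884). Altogether 12274 of 15544 tested genes passed, 5933 higher and 6341 lower at 15 °C, 1881 and 1697 by at least 2-fold.

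In old octr-1 mutants the same question was asked of 15 °C against 20 °C. All 21 aspartyl and cysteine proteases were lower (21 adjusted over the list alone, camera adjusted p = 1.13e-10, and adjusted p = 0.305 with an estimated correlation). Of these, cpz-2 (4.13-fold), asp-13 (4.08-fold) and cpr-3 (3.29-fold) were lower. PMK-1 immune effectors were likewise lower in all 19 measured members (19 adjusted over the list alone, camera adjusted p = 2.21e-08, and adjusted p = 0.305 with an estimated correlation), among them lys-2 at 4.97-fold and C17H12.8 at 3.81-fold. Lysozymes and saposin-like proteins counted 0 higher and 29 lower of 32 measured, 0 and 30 adjusted over the list alone (camera adjusted p = 3.34e-11, and adjusted p = 0.305 with an estimated correlation). ilys-3 was 22-fold lower, at 149 ± 17.8 against 3273 ± 138 normalized reads (SD, n = 5), and lys-3 3.80-fold. C-type lectins counted 11 higher and 74 lower of 116 measured, 12 and 74 adjusted over the list alone (camera adjusted p = 8.59e-07, and adjusted p = 0.305 with an estimated correlation). Of these, clec-47 (12.4-fold), clec-5 (5.53-fold) and clec-150 (3.86-fold) were lower.

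Synaptic machinery counted 24 higher and 2 lower of 30 measured, 24 and 2 adjusted over the list alone in the mutants at 15 °C over 20 °C (camera adjusted p = 1.41e-08, and adjusted p = 0.305 with an estimated correlation). Here ida-1 (2.15-fold), unc-13 (1.94-fold) and unc-2 (1.88-fold) were higher. Intestine genes counted 2 higher and 19 lower of 21 measured, 2 and 19 adjusted over the list alone (camera adjusted p = 4.24e-08, and adjusted p = 0.319 with an estimated correlation). Of these, ftn-1 (3.76-fold), fat-2 (3.30-fold) and lbp-6 (2.74-fold) were lower. Targets repressed by DAF-16 counted 0 higher and 10 lower of 12 measured, 0 and 10 adjusted over the list alone (camera adjusted p = 1.46e-05, and adjusted p = 0.305 with an estimated correlation). Here dod-22, the esterase ges-1 and dod-23 were 4.98-fold, 3.66-fold and 2.25-fold lower. UDP-glucuronosyltransferases counted 13 higher and 44 lower of 61 measured, 13 and 44 adjusted over the list alone (camera adjusted p = 1.69e-05, and adjusted p = 0.319 with an estimated correlation). Of these, ugt-63 (5.82-fold), ugt-41 (3.65-fold) and ugt-25 (2.73-fold) were lower. Within the limits on mean and overlap, the largest rises were in F40H7.12 (3.41 ± 0.05), fbxa-43 (3.27 ± 0.11), Y71H2AR.2 (2.85 ± 0.09), T20D4.7 (2.81 ± 0.06), W04G5.7 (2.70 ± 0.10) and chil-27 (2.64 ± 0.10) and the deepest falls in ilys-3 (-4.46 ± 0.07), C50F7.5 (-3.41 ± 0.16), C30G12.2 (-3.10 ± 0.13), Y54G2A.57 (-3.04 ± 0.06), C32H11.4 (-3.02 ± 0.19) and ZK355.3 (-2.99 ± 0.09), as log2 fold change ± SE. The residual octr-1 signal was 1.41-fold higher at 15 °C (limma adjusted p = 0.00629). limma called 10699 of 16083 tested genes, 5095 higher and 5604 lower at 15 °C, and 750 and 1421 changed at least 2-fold.

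Old mutants at 15 °C were also set against those at 25 °C. Synaptic machinery had 28 of 31 members higher and 0 lower (30 higher adjusted over the list alone, adjusted p = 0.0105 with an estimated correlation). Of these, ida-1, unc-2 and the proprotein convertase egl-3 were 2.83-fold, 2.79-fold and 2.71-fold higher. Histones counted 32 higher and 3 lower of 40 measured, 32 and 3 adjusted over the list alone (camera adjusted p = 1.36e-05, and adjusted p = 0.7 with an estimated correlation). Here hil-3 (5.71-fold), hil-2 (5.18-fold) and his-24 (3.96-fold) were higher. Cytosolic chaperones counted 14 higher and 2 lower of 18 measured, 14 and 2 adjusted over the list alone (camera adjusted p = 0.00265, and adjusted p = 0.7 with an estimated correlation), including hsp-110 at 2.46-fold higher and the chaperonin subunits cct-2 and cct-8 at 1.89-fold and 1.87-fold. Autophagy and lysosome genes counted 20 higher and 8 lower of 32 measured, 21 and 8 adjusted over the list alone (camera adjusted p = 0.00858, and adjusted p = 0.7 with an estimated correlation). Here the cargo receptor sqst-1 rose 2.87-fold, from 10060 ± 244 to 28890 ± 1702 normalized reads (SD, n = 5), epg-2 2.76-fold and atg-2 2.29-fold. Ribosomal proteins counted 60 higher and 5 lower of 79 measured, 60 and 5 adjusted over the list alone, around a median of 0.33 (camera adjusted p = 2.07e-05, and adjusted p = 0.7 with an estimated correlation). Of these, rpl-12 (1.81-fold), rpl-4 (1.64-fold) and rpl-20 (1.59-fold) were higher. With library size as the only scaling, the medians went from 0.478 to 0.306 for chaperones, from 0.305 to 0.133 for autophagy genes and from 0.333 to 0.161 for ribosomal proteins.

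Muscle contractile proteins counted 5 higher and 24 lower of 31 measured, 5 and 24 adjusted over the list alone in mutants at 15 °C against 25 °C (camera adjusted p = 0.000164, and adjusted p = 0.7 with an estimated correlation). Of these, the troponins tnt-4 and tni-4 and the pharyngeal myosin myo-1 were 7.97-fold, 6.65-fold and 5.81-fold lower. Collagens counted 64 higher and 9 lower of 105 measured, 64 and 9 adjusted over the list alone (camera adjusted p = 0.00129, and adjusted p = 0.7 with an estimated correlation). Here col-113 (4.67-fold), dpy-17 (3.79-fold) and col-99 (3.06-fold) were higher. UDP-glucuronosyltransferases counted 10 higher and 44 lower of 62 measured, 10 and 45 adjusted over the list alone (camera adjusted p = 0.000164, and adjusted p = 0.7 with an estimated correlation). Here ugt-32 and ugt-41 were 17.6-fold and 4.47-fold lower and ugt-50 2.92-fold higher. The genes that rose the most within the limits on mean and overlap were F40H7.12 (5.71 ± 0.06), F56A6.5 (5.13 ± 0.09), R08E5.3 (4.09 ± 0.10), Y71H2AM.25 (3.90 ± 0.09), asah-1 (3.82 ± 0.14) and unc-39 (3.78 ± 0.07), where asah-1 is an acid ceramidase and unc-39 a homeobox factor. Those that fell the most within them were ilys-2 (-5.92 ± 0.15), C15H9.11 (-5.80 ± 0.08), C50F7.5 (-5.65 ± 0.17), Y37H2C.1 (-5.10 ± 0.09), oac-14 (-4.83 ± 0.13) and T28B4.4 (-4.69 ± 0.11), again as log2 fold change ± SE. octr-1 reads were 1.34-fold higher at 15 °C (limma adjusted p = 0.0102). In limma, 12857 genes of 16285 tested passed, 6284 higher and 6573 lower at 15 °C, 1914 and 1928 at least 2-fold.

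The last pair, old mutants at 25 °C against 20 °C, had a large fall of acdh-1 at the higher temperature. acdh-1 was 43.8-fold lower, at 73.4 ± 10.8 against 3233 ± 209.9 normalized reads (SD, n = 5). Within the limits on mean and overlap, the 6 deepest falls, as log2 fold change ± SE, were in acdh-1 (-5.45 ± 0.08), lipl-1 (-5.07 ± 0.12), ilys-5 (-5.04 ± 0.10), asah-1 (-4.89 ± 0.08), C24B9.3 (-4.78 ± 0.10) and F42A10.7 (-4.76 ± 0.08), where lipl-1 is a lysosomal lipase. Proteases counted 2 higher and 19 lower of 23 measured, 2 and 19 adjusted over the list alone (camera adjusted p = 4.29e-08, and adjusted p = 0.166 with an estimated correlation). Of these, cpr-1 (15.4-fold), asp-3 (10.2-fold) and asp-5 (6.03-fold) were lower. The lysozyme and saposin-like list counted 6 higher and 27 lower of 33 measured, 6 and 27 adjusted over the list alone (camera adjusted p = 1.93e-06, and adjusted p = 0.166 with an estimated correlation). Of these, lys-4 (24.1-fold), lys-2 (10.8-fold) and spp-5 (4.0-fold) were lower. PMK-1 immune effectors counted 2 higher and 15 lower of 19 measured, 2 and 15 adjusted over the list alone (camera adjusted p = 2.03e-05, and adjusted p = 0.166 with an estimated correlation). Of these, dod-24 and thn-2 were 22.6-fold and 12-fold lower. All 6 vitellogenins were lower (6 adjusted over the list alone, camera adjusted p = 7.42e-06, and adjusted p = 0.18 with an estimated correlation). Here vit-1 (16-fold), vit-5 (4.29-fold) and vit-2 (3.79-fold) fell.

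Ribosomal proteins counted 4 higher and 65 lower of 79 measured, 4 and 65 adjusted over the list alone in mutants at 25 °C, with a median of -0.35 (camera adjusted p = 4.29e-08, and adjusted p = 0.297 with an estimated correlation). Here rpl-26 (1.84-fold), rpl-20 (1.72-fold) and rps-19 (1.70-fold) were lower. Collagens counted 6 higher and 70 lower of 110 measured, 6 and 70 adjusted over the list alone (camera adjusted p = 1.46e-06, and adjusted p = 0.177 with an estimated correlation). Of these, col-140 (14.7-fold), col-122 (5.98-fold) and dpy-17 (3.47-fold) were lower. Genes of glycolysis, gluconeogenesis and the glyoxylate cycle counted 2 higher and 19 lower of 25 measured, 2 and 19 adjusted over the list alone (camera adjusted p = 1.65e-05, and adjusted p = 0.192 with an estimated correlation), among them the alcohol dehydrogenase sodh-1 at 4.47-fold lower, the aldolase aldo-2 at 2.27-fold lower and the dehydrogenase gpd-4 at 2.0-fold lower. Oocyte and eggshell genes counted 2 higher and 22 lower of 27 measured, 2 and 22 adjusted over the list alone (camera adjusted p = 8.77e-05, and adjusted p = 0.259 with an estimated correlation). Here cav-1 (5.61-fold), cbd-1 (2.36-fold) and mbk-2 (1.6-fold) were lower. With library size as the only scaling, the medians went from -0.352 to -0.135 for ribosomal proteins, from -0.455 to -0.239 for oocyte genes and from -0.530 to -0.313 for glycolysis genes. The largest rises within the same limits were in C15H9.11 (4.73 ± 0.07), T28B4.4 (4.24 ± 0.07), Y37H2C.1 (4.12 ± 0.08), C01G10.5 (3.95 ± 0.07), F18E3.12 (3.39 ± 0.10) and C34B7.1 (3.09 ± 0.07). octr-1 stood at 35.5 ± 4.38 against 34.4 ± 5.42 normalized reads, which limma did not separate (adjusted p = 0.768). With limma 12136 of 16262 tested genes passed, 6060 higher and 6076 lower at 25 °C, 939 and 1295 by at least 2-fold. The sample columns of this table carried each other's group names and were exchanged before the test, and with the names as given every direction here is reversed.

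Whether the octr-1 effect in old animals differed between temperatures was tested as the difference between the genotype effects at 2 temperatures, which rest on separate libraries. The day of collection differed along with the temperature, so these tests cannot tell the 2 apart. Between 25 and 20 °C, lys-4, a lysozyme, fell by 4.68 on the log2 scale at 25 °C against -0.82 at 20 °C, a difference of -3.86 ± 0.08 (SE, limma adjusted p = 1.34e-33). The propionate shunt gene acdh-1 had the largest difference of the 6 genes with the smallest p, -5.08 ± 0.09. The log2 effects at 25 and 20 °C of all 6 were lys-4 (-4.68 and -0.82), F57F5.1 (-3.95 and -0.80), asp-2 (-3.76 and -0.59), T21H3.1 (-3.08 and -0.30), K12H4.7 (-3.98 and -0.48) and acdh-1 (-5.94 and -0.86). In total 8944 of 15420 genes differed in their genotype effect, 4032 with a higher and 4912 with a lower value at 25 °C.

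Between 15 and 25 °C, the folate transporter folt-2 did not respond to genotype at 15 °C (0.04 ± 0.11, log2 ± SE) and fell by 4.90 at 25 °C, with a limma adjusted p of 2.69e-26 for the difference. C27H5.6 was lower in mutants at 15 °C and higher at 25 °C, and the fatty acid synthase fasn-1 was higher at 15 °C and lower at 25 °C. The effects at 15 and 25 °C of the 6 leading genes were folt-2 (0.04 and -4.90), C27H5.6 (-1.24 and 2.38), fbn-1 (-0.07 and -1.74), F37H8.5 (-0.33 and -2.89), fasn-1 (0.53 and -1.07) and C23H5.8 (-0.48 and -4.44), where fbn-1 encodes a fibrillin-like matrix protein. The test found 9352 of 15292 genes, 4562 with a higher and 4790 with a lower genotype effect at 15 °C. Between 15 and 20 °C there were 3501 of 15370, 1563 higher and 1938 lower at 15 °C. The trehalase tre-5, the amide hydrolase faah-2, the thioredoxin trx-3 and the lysozyme lys-3 were lower in mutants at 15 °C and higher at 20 °C, with effects at 15 and 20 °C of tre-5 (-0.61 and 1.32), faah-2 (-0.67 and 0.65), Y41C4A.11 (0.83 and 2.12), Y54G2A.57 (-0.01 and 2.35), trx-3 (-1.09 and 0.57) and lys-3 (-1.0 and 0.50) and a limma adjusted p of at most 6.23e-15.

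Whether the octr-1 effect depended on age was tested at 20 °C. The desaturase fat-7 was higher in young mutants and lower in old ones, by 0.52 and -1.85 on the log2 scale, and the P-glycoprotein pgp-5 by 1.08 and -1.05. B0035.13, T15B7.1 and Y45F10C.4 also changed direction, and F23D12.11 was lower at both ages, with old and young effects of B0035.13 (-1.63 and 0.93), T15B7.1 (-1.04 and 0.71), Y45F10C.4 (-0.82 and 0.47) and F23D12.11 (-2.04 and -0.29) and a limma adjusted p of at most 7.32e-16 for all 6. Altogether 4479 of 13005 genes had a different genotype effect at the 2 ages, 1975 higher and 2504 lower in old animals.

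**Figure D4:**
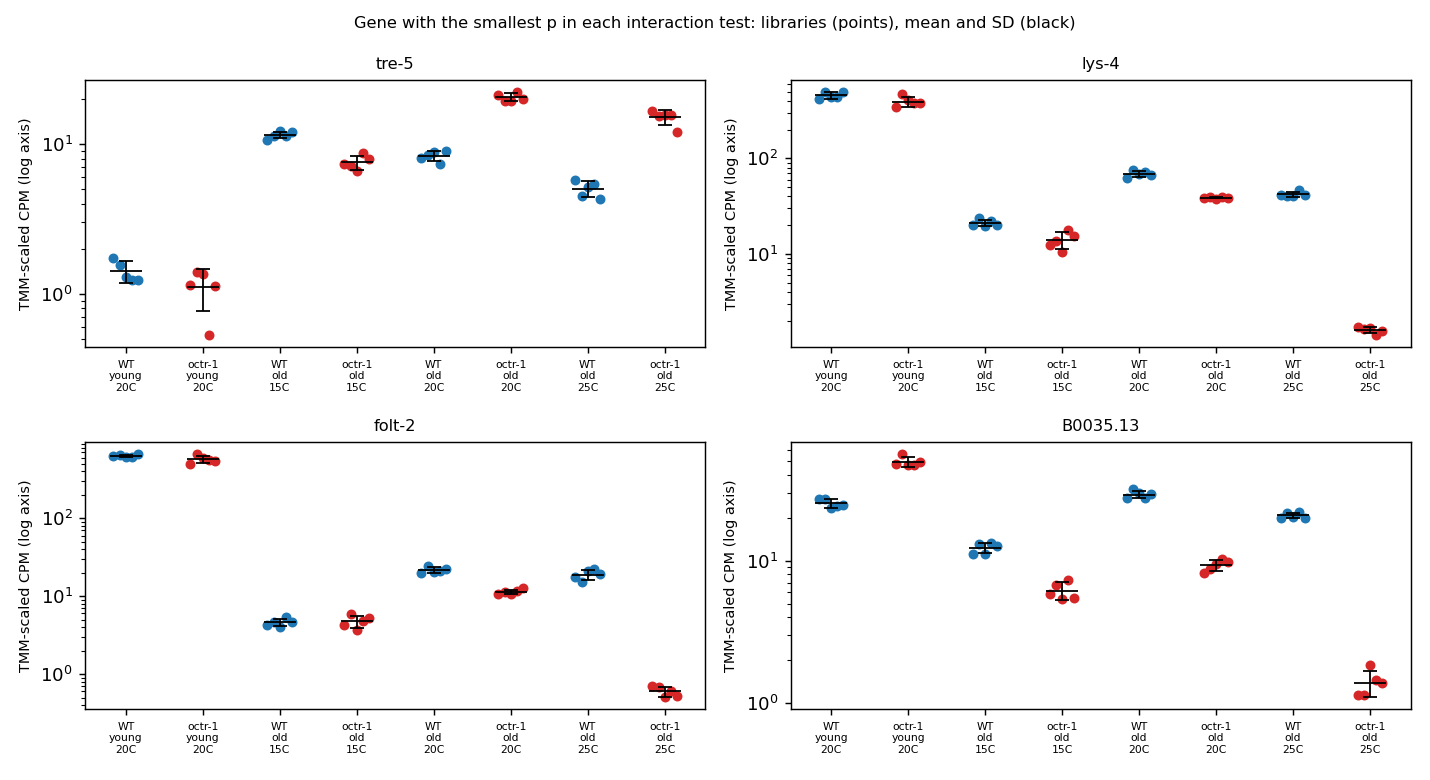
TMM-scaled CPM (log axis) of the gene with the smallest p in each of the 4 tests of a difference between genotype effects, in the 8 groups on the x axis, with the 5 libraries of each group as points (wild type in blue, octr-1 in red) and the mean and SD in black. At 25 °C, lys-4 has a mean of 42.0 in the wild type and 1.6 in the mutant.

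Genotype effects from separate libraries were set side by side across genes, which are not independent replicates. The log2 fold changes in old animals at 20 and 15 °C had a Pearson r of 0.688 and a Spearman rho of 0.572 over 15370 genes, and 90.5% of the 4846 genes called in both had the same sign. In the same order, old animals at 20 and 25 °C had 0.676, 0.521 and 77.7% of 6061, and those at 15 and 25 °C 0.549, 0.409 and 69.0% of 6462. Young animals and old ones had 0.494, 0.235 and 73% of 3116 at 20 °C, 0.381, 0.146 and 64.8% of 3326 with old animals at 15 °C, and 0.272, 0.242 and 73.2% of 4671 with those at 25 °C. The responses of the 2 genotypes to 15 against 20 °C had 0.838, 0.829 and 97.4% of 8068, and those to 15 against 25 °C 0.737, 0.733 and 88.5% of 10205, where the 2 pairs share the libraries at 15 °C. Of 12837 genes tested in all 4 genotype comparisons, 619 were higher and 531 lower in the mutant each time. Chosen after their values were seen, and below the limit of 2 log2 CPM for the largest changes, Y102A5C.36 had log2 fold changes of -8.30 to -7.41 and frm-5.2 of 3.85 to 5.06 in the 4 comparisons.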

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

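Chosen only after the result was seen were the tests of male neuron genes in old animals, of reads shared between near-identical genes, of stage, of mislabelled libraries and of depth. The 4 tests of a difference between genotype effects found 3501 genes between 15 and 20 °C, 8944 between 25 and 20 °C, 9352 between 15 and 25 °C and 4479 between ages. Counts as high as the real ones came up in 1 of 100 regroupings within the tables, the real one included, for each of the 4 tests. The highest count of the other regroupings was 2589 for 15 against 20 °C, 433 for 15 against 25 °C and 0 for the other 2 tests. Each other regrouping mixed both genotypes within each comparison, so the genotype difference itself widened the spread. These regroupings therefore do not show what equal genotype effects would give, and their low counts are no measure of false calls.

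The genes of smallest p differed between 15 and 20 °C, as differences of log2 genotype effects, by these amounts: tre-5 (-1.93), faah-2 (-1.32), Y41C4A.11 (-1.29), Y54G2A.57 (-2.36), trx-3 (-1.66) and lys-3 (-1.50). Between 25 and 20 °C they were lys-4 (-3.86), F57F5.1 (-3.15), asp-2 (-3.17), T21H3.1 (-2.78), K12H4.7 (-3.51) and acdh-1 (-5.08). Between 15 and 25 °C they were folt-2 (4.94), C27H5.6 (-3.62), fbn-1 (1.67), F37H8.5 (2.56), fasn-1 (1.61) and C23H5.8 (3.96), and between old and young animals B0035.13 (-2.55), T15B7.1 (-1.75), pgp-5 (-2.13), F23D12.11 (-1.74), Y45F10C.4 (-1.28) and fat-7 (-2.37).

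A single library stood far from the other 4 of its group, by Dixon's ratio of gap to range above 0.71, in 40 of 855 groups of 5 values, and chance gives about 5% of them. In young wild-type animals these were replicate 1 for gipc-2 (0.792), gsp-3 (0.85), msp-38 (0.726) and msp-55 (0.725) and replicate 4 for octr-1 (0.751). In young mutants these were replicate 2 for B0035.13 (0.749), octr-1 (0.765) and rpn-5 (0.821). In old wild-type animals at 15 °C these were replicate 3 for msp-57 (0.73) and replicate 4 for cpr-6 (0.79) and rpl-22 (0.711). In old wild-type animals at 20 °C these were replicate 1 for acdh-1 (0.782), replicate 3 for col-106 (0.726), hsp-16.41 (0.919) and lys-7 (0.832) and replicate 4 for cct-2 (0.804), col-99 (0.876), rpl-31 (0.772) and Y58A7A.5 (0.758). In old wild-type animals at 25 °C these were replicate 1 for T21H3.1 (0.741), replicate 2 for msp-36 (0.756), replicate 3 for nhr-67 (0.741) and replicate 4 for lys-4 (0.841), spe-6 (0.765) and unc-2 (0.716). In old mutants at 15 °C these were replicate 1 for the number of reads (0.729) and dod-22 (0.744) and replicate 4 for faah-2 (0.733) and tnt-4 (0.75). In old mutants at 20 °C these were replicate 1 for aldo-2 (0.888), hsp-110 (0.781), mtl-1 (0.801) and ugt-25 (0.915), replicate 2 for T20D4.7 (0.764), replicate 4 for fbxa-43 (0.714) and spp-17 (0.822) and replicate 5 for msp-57 (0.892). In old mutants at 25 °C these were replicate 1 for C27H5.6 (0.957) and replicate 3 for msd-4 (0.746) and unc-39 (0.729).

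More sperm genes were called higher than lower in mutants in each of the 4 genotype comparisons. A difference in stage of the young cultures alone is argued against by the old animals, where the lowest median log2 fold change of the list was 1.38. Reads shared between near-identical genes stay open. List members outside the msp and nspd families had a median of 1.0 in young animals with quartiles of 0.16 and 1.35 (15 of 25 higher and 4 lower). The rounded median meets the bound of 1 set against this explanation. A lower quartile above 0.5 was also required, beyond the bound as first written, and it was not reached. Males in the mutant cultures stay open too, since 0 male neuron genes passed the filter in young animals and in old animals their median was 0.51 over 8 genes at 20 °C, 0.54 over 9 at 15 °C and 1.32 over 9 at 25 °C. The value at 25 °C lies past the bound of 1 set for males, and the other 2 lie between it and the bound of 0.5 set against them. Within a genotype the list did not follow the sperm list between 15 and 25 °C, with 8 of 8 male neuron genes called higher at 15 °C and a sperm median of -0.575 in the wild type, and medians of 0.57 and -0.514 in mutants. Between 15 and 20 °C the signs were the same (1.0 and 0.468, 0.83 and 0.060), as between mutants at 25 and 20 °C (0.23 and 0.513). A biological effect of octr-1 on sperm genes is an open hypothesis that was not tested.

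The genotype comparison at 25 °C called more genes than those at 15 and 20 °C and had acdh-1 among its deepest falls. Its median standard error was smaller, 0.067 against 0.083 at 15 °C and 0.077 at 20 °C, which by itself raises the count of called genes. Called genes that changed at least 2-fold were also more numerous, 2726 against 825 at 15 °C and 886 at 20 °C. Libraries exchanged between the genotypes at 25 °C are argued against by octr-1, whose lowest wild-type CPM was 4.934 times the highest mutant CPM. An exchange between temperatures is not tested by this, since octr-1 was not called between 25 and 20 °C in mutants or the wild type. A difference in depth is argued against by a ratio of mean depths of 1.004. A difference in vitamin B12 supply between the cultures stays open. The 4 other propionate shunt genes had a median log2 fold change of -0.67 (4 of 4 lower, 2 of them matched through older names). The methionine cycle list, which also held the linked genes mel-32 and pmp-5, had a median of -0.35 (7 of 7 lower). Its members ran from mtrr-1 at -0.09 to pmp-5 at -2.86. Both medians lie between the bounds set for and against a difference in vitamin B12 supply. The difference in day of collection and a biological effect of octr-1 at 25 °C also stay open and were not tested.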

How the results depend on the processing

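Added after the data were seen were edgeR with TMM on recovered reads, column names as given, library size as the only scaling, and the gene lists with TMM or without each library. Counts of called genes stayed within 1.14 times the reported count in the 9 comparisons and within 1.16 times in the 4 tests of a difference, over the alternatives that were run. For young animals the range was 5370 to 6465 over other settings and 5000 to 5884 without 1 library. For the genotype comparison at 25 °C it was 11977 to 13463 and 11971 to 12096. The age comparisons reached 1.28 times without a filter. Libraries of the same number correlated above 0.1 in at most 3 of 5 pairs of a comparison, with r up to 0.339, so the libraries were tested as unpaired. A replicate block gave 5815 genes in young animals and 11977 at 25 °C, and took the list calls of the genotype comparison at 20 °C from 15 to 10. The share of called genes that were higher lay below 50% with limma in all 9 comparisons and above it with edgeR or DESeq2 in 7 of them, for example 44.9% and 52.7% (TMM) in young animals. The authors' DESeq2 called 5618 genes in young animals, 5251 of them also called here, and every gene called in both had the same sign in each of the 9 comparisons.

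With column names as given, the comparison of mutants at 25 and 20 °C again gave 12136 genes, with every direction reversed by construction. With an estimated correlation, camera called fewer lists, 2 in place of 19 (octr-1 young 20C vs WT young 20C), 0 in place of 15 (octr-1 old 20C vs WT old 20C), 0 in place of 15 (octr-1 old 15C vs WT old 15C), 7 in place of 26 (octr-1 old 25C vs WT old 25C), 3 in place of 23 (WT old 15C vs WT old 20C), 2 in place of 21 (WT old 15C vs WT old 25C), 0 in place of 22 (octr-1 old 15C vs octr-1 old 20C), 1 in place of 15 (octr-1 old 15C vs octr-1 old 25C) and 0 in place of 22 (octr-1 old 25C vs octr-1 old 20C). That setting estimates the correlation between genes in each list, and how much of the drop comes from this correlation was not tested. Library size as the only scaling moved the median log2 fold change of all genes by over 0.1 in 3 comparisons, to 0.1958 (genotype at 25 °C), -0.1925 (mutants, 15 against 25 °C) and 0.2283 (mutants, 25 against 20 °C). In the 9 comparisons with a table, the camera lists named in the report kept the sign of their medians, but small medians changed in size, down to -0.046 from -0.146 for the germline list of young animals.

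octr-1 was not called between mutants at 25 and 20 °C, and its log2 fold change there was -0.029 to 0.111 without 1 library, with -0.029 without replicate 5 at 20 °C and 0 without replicate 2 at 25 °C. In the wild type at 25 and 20 °C it was -0.006 to 0.048, with -0.006 without replicate 3 at 20 °C, and the sign is therefore undecided. In the wild type at 15 and 20 °C octr-1 became called in the fit of all 8 groups, at -0.153. The cause was not tested.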

Other observations

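Chosen only after the result was seen was the test of repeated sequencing of 1 library. With age at 20 °C, B0238.12 rose 224-fold in the wild type, from 0.276 ± 0.104 to 61.5 ± 4.66 TMM-scaled CPM (SD, n = 5), irg-2 121-fold, the non-coding tts-1 90.9-fold and the lysosomal lipase lipl-1 89-fold. The chemoreceptor sri-40 fell 121-fold and the collagens col-93 and col-20 fell 117-fold and 65.5-fold. With TMM scaling, octr-1 rose 3.478-fold (edgeR adjusted p = 5.14e-12). Its young and old means were 1.529 and 5.368 TMM-scaled CPM, against 1.251 and 6.56 CPM by library size alone. TMM thus lowered old values against young ones, and the lists below were not computed without it. A small median, such as -0.524 for the log2 fold change of the germline list, may therefore depend on the scaling. The 8 lists of smallest camera p, each with members higher and lower of those measured, the same adjusted over the list alone, and camera's adjusted p at the preset and at an estimated correlation, were ribosomal proteins (1 and 77 of 78, 1 and 77, 3.67e-21, 0.278), respiratory chain subunits (0 and 32 of 32, 0 and 32, 2.37e-11, 0.278), proteasome subunits (0 and 32 of 32, 0 and 32, 2.37e-11, 0.278), F-box proteins (207 and 32 of 270, 207 and 32, 9.44e-08, 0.278), germline and meiosis genes (1 and 31 of 35, 1 and 31, 9.44e-08, 0.278), cytosolic chaperones (1 and 16 of 18, 1 and 16, 4.12e-06, 0.278), muscle contractile proteins (4 and 22 of 31, 4 and 22, 1.45e-05, 0.419) and neuropeptides and insulins (73 and 9 of 92, 73 and 9, 5.73e-05, 0.282). edgeR called 12534 of 14673 genes (6759 higher and 5775 lower).

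In mutants the lysozyme ilys-3 rose 272-fold with age, from 0.294 ± 0.119 to 83.2 ± 3.39 TMM-scaled CPM (SD, n = 5), the metallothionein mtl-1 116-fold and lys-3 90.3-fold. The collagen col-93 fell 443-fold and the saposin-like spp-17 113-fold. The residual octr-1 signal rose 1.765-fold (edgeR adjusted p = 0.00126), with overlap between the ages. Its young and old means were 0.4555 and 0.8162 TMM-scaled CPM, against 0.3774 and 0.9812 CPM by library size alone. Small list changes with age may thus depend on the scaling in mutants too. Given in the same way, the 8 lists were ribosomal proteins (1 and 77 of 78, 1 and 77, 1.65e-21, 0.279), respiratory chain subunits (0 and 32 of 32, 0 and 32, 4.05e-12, 0.279), proteasome subunits (0 and 32 of 32, 0 and 32, 2.16e-11, 0.279), muscle contractile proteins (5 and 25 of 31, 5 and 25, 1.58e-05, 0.387), cytosolic chaperones (2 and 16 of 18, 2 and 16, 1.73e-05, 0.279), aspartyl and cysteine proteases (3 and 18 of 21, 3 and 18, 1.76e-05, 0.28), intestine genes (3 and 18 of 21, 3 and 18, 1.76e-05, 0.279) and F-box proteins (185 and 42 of 275, 184 and 42, 3.51e-05, 0.28). edgeR called 13200 of 15402 genes (6980 higher and 6220 lower). In the wild type at 25 against 20 °C, F20E11.17 rose 9.15-fold and rpr-1 6.21-fold, while gba-2 fell 12-fold, fmo-2 11.9-fold and dhs-26 8.13-fold. In the same form, the 8 lists were sperm genes (38 and 2 of 52, 38 and 3, 8.44e-06, 0.57), cuticle collagens (77 and 25 of 133, 77 and 25, 0.000208, 0.603), histones (3 and 26 of 36, 3 and 27, 0.000208, 0.54), germline and meiosis genes (22 and 2 of 35, 23 and 3, 0.000353, 0.57), small heat shock proteins (8 and 0 of 10, 8 and 0, 0.000562, 0.132), muscle contractile proteins (20 and 3 of 31, 21 and 3, 0.000729, 0.676), ribosomal proteins (3 and 40 of 78, 3 and 37, 0.00618, 0.676) and nuclear hormone receptors (30 and 98 of 196, 30 and 98, 0.00969, 0.54), with a median log2 fold change of 0.983 for sperm genes. edgeR called 9785 of 15314 genes (4619 higher and 5166 lower).

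Other groupings of the same libraries, 100 drawn at random for the 9 comparisons and 40 for the 3 in this part, were compared with the real ones. The real count of called genes was reached by 1 grouping, the real one, in each of these 12 comparisons, from 5722 to 13200 genes against at most 1 in any other grouping. A random division of these libraries is thereby excluded as the source, while differences between cultures are not, if the libraries of a group share 1 culture. Each other grouping mixed libraries of both real groups, whose difference then widened its spread. Its low count is therefore no measure of false calls. For gene lists at camera's preset correlation, the groupings with as many lists as the real one, the real one included, were 14 (octr-1 young 20C vs WT young 20C, 19 lists and at most 23 in others), 13 (octr-1 old 20C vs WT old 20C, 15 lists and at most 18 in others), 32 (octr-1 old 15C vs WT old 15C, 15 lists and at most 25 in others), 2 (octr-1 old 25C vs WT old 25C, 26 lists and at most 26 in others), 4 (WT old 15C vs WT old 20C, 23 lists and at most 24 in others), 8 (WT old 15C vs WT old 25C, 21 lists and at most 25 in others), 17 (octr-1 old 15C vs octr-1 old 20C, 22 lists and at most 26 in others), 4 (octr-1 old 15C vs octr-1 old 25C, 15 lists and at most 15 in others) and 1 (octr-1 old 25C vs octr-1 old 20C, 22 lists and at most 21 in others). At the limit of under 5 of 100 set before the data were seen, a random division can be excluded for the list counts of 4 comparisons (octr-1 old 25C vs WT old 25C, WT old 15C vs WT old 20C, octr-1 old 15C vs octr-1 old 25C and octr-1 old 25C vs octr-1 old 20C) and not for the other 5. Even in these 4, another grouping tied the real list count in 2 and passed it in 1.

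Replicates of a group lay close together, with a median coefficient of variation beyond counting of 2.06% to 4.82%. One library sequenced 5 times is argued against, since the lowest chi-square per degree of freedom of any replicate pair was 1.941 and the highest 22.1. Separate preparations of 1 culture were not tested. Differences in strain background, for example for Y102A5C.36 and frm-5.2, were not tested either.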
